A study of Drosophila melanogaster with 3 samples.

How the data were processed

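Chromatin of transgenic flies expressing acj6 tagged with GFP was sonicated to fragments of 200 to 800 bp, per the labels, and immunoprecipitated with an antibody against GFP. The 3 samples are biological replicates 1, 2 and 3 of 1 group of whole white prepupae of mixed sex. The reads were aligned to dm6 and, separately, to dm3, per the labels. The aligner, peak caller, their versions and the IDR threshold are not given in the sources used here. The control experiment named in the labels was not analysed here.

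For each build the authors deposited 5 peak lists: 1 per replicate and 1 from the pooled alignments of the 3 replicates, each of 30000 regions that include background and serve as input to the IDR procedure (irreproducible discovery rate, which ranks peaks by how well replicates repeat them), and 1 list of peaks past the IDR threshold. Per the text files deposited with the lists, each replicate list derives from its own alignment and 1 control file shared by all replicates, and the IDR list derives from the replicate lists and the pooled list. Each peak has the signal value that the authors' caller gave it, which is not scaled between lists and was used here only to rank peaks within a list. The deposited −log10 q values reach a ceiling in each list (4.18 in the dm6 IDR list, which is also its median), so that they rank no strong peaks and were used only to describe the lists. The commonest region width was 390, 384 and 410 bp in replicates 1, 2 and 3 and 420 bp in the pooled and IDR lists of dm6. The dm6 IDR list repeats 23 intervals with other summits and has 6 summits outside their interval, and all were kept as deposited.

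The deposited lists give no read counts, so the depth of each replicate is unknown and the precision of a share comes from the number of peaks (8248) and the spread between replicates. Positions were set against NCBI's Release 6 genome sequence and Ensembl's annotation of that release, both in dm6 coordinates. The peaks of each arm lie within the length of the arm. The annotation gave 13945 protein-coding genes on arms 2L, 2R, 3L, 3R, 4 and X. Peaks of the dm3 lists outside these arms entered no comparison.

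Replicates were compared over their 8248 strongest peaks, the length of the IDR list. A peak counted as shared when a single peak of the other list covered at least 50% of its length. A summit within 500 bp of a protein-coding TSS was called TSS-proximal and any other distal, and a gene was called bound when a summit lay within 1 kb of any of its TSSs. Random positions came from circular shifts within each arm (1000 draws, 100 for the agreement of replicates). Gene lists (22) and motifs (15) were fixed before the data were examined, as were the tests and most alternatives. Gene lists were tested with two-sided Fisher's exact tests, and motifs and 6-mers with two-sided exact McNemar tests of the 100 bp on each side of a summit against a window of the same width 1 kb to the right. P-values were adjusted by Benjamini and Hochberg within the lists, the motifs and the 2080 6-mers, with a threshold of 0.05. Genes and peaks are not independent replicates, so these p-values describe the lists and not variation between animals. Intervals of shares are exact 95% binomial intervals and cover counting error only.

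Genes were named by a rule fixed beforehand: acj6, the genes at the 12 strongest TSS-proximal and 6 strongest distal IDR peaks covered in all 3 replicates, up to 4 members with the strongest peaks of a list bound more often and up to 2 of a list bound less often, and the 6 6-mers with the highest and the 4 with the lowest ratio. Members of the ecdysone and neuron identity lists were named after their values were seen. Alternatives covered the overlap that counts as shared, stronger peaks, peaks found in all 3 replicates, leaving out each replicate, other TSS distances, weak pooled peaks as background (20504 that overlap no IDR peak), other control windows, GC matching in bins of 2%, gene length and TSS number as covariates, and the dm3 lists.

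The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for the plots. They were tested on simulated peak sets, on random gene lists and on real sequence away from the summits. Of 40 random sets of 8000 peaks, 2 had a permutation p under 0.05 against 200 shifts, and of 200 random lists of 60 genes 5% had a Fisher p under 0.05. Lists of 60 genes with 50% bound were called higher in 100% of draws and lists with 40% bound in 0%. Every draw of a setting had the same number of bound genes and the same other lists. Its call was thus fixed, and these shares are not detection rates. Calls of less binding were not covered by these draws. The draws set no limit for the real lists either, because the adjusted p of a list depends on the p-values of the other lists. No motif of 15 and no 6-mer of 2080 was called between real windows away from the summits, with nothing planted. Neither set of windows was centred on summits, so this check cannot show calls that come from the base composition of summits. Coverage calls were the same as those of bedtools 2.31.1 for all 8248 peaks.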

Results

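The data were peak lists from chromatin immunoprecipitation and sequencing (ChIP-seq) of acj6, a class IV POU-homeodomain transcription factor first known from odour responses and the wiring of olfactory neurons. The flies were a transgenic Drosophila melanogaster line that stably expressed acj6 with GFP at its C-terminus, and the immunoprecipitation was made with an antibody against GFP. Whole animals of both sexes were collected as white prepupae, the stage at which the larva stops moving and forms the puparium. There was 1 group of 3 biological replicates and no second group, so the comparisons were between replicates, between parts of the peak list and against positions chosen at random. The labels do not say whether the 3 replicates came from separate cultures. Each replicate had a list of 30000 regions ranked by signal, and the list of reproducible peaks (the IDR list) held 8248 peaks in dm6 coordinates. Read depth was unknown, since the files give no counts. The equal length of the replicate lists and the ranks within them carry no measure of it. All 3 replicates share 1 control file, so that features of the control enter every list.

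The tagged gene itself was not among the strongest regions. It is also present on the transgene, so regions here may draw signal from added copies, which was not examined. The IDR list held 2 peaks in acj6 (FBgn0000028, dm6 X:15350239 to 15379064, minus strand) and the 5 kb around it. Both lay in an intron, with summits at 15363866 and 15364703, and ranked 6022 and 4410 of 8248 by the authors' signal value. The nearest annotated transcription start site (TSS) of a protein-coding gene was that of Pp1-13C, a protein phosphatase gene nested in acj6, at 2805 and 3642 bp. In each of the 3 replicates, 11 of the 30000 regions fell in this interval and 2 of these were among the 8248 strongest, the best of them at rank 6230 in replicate 1, 4022 in replicate 2 and 3819 in replicate 3.

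The same places were the strongest in all 3 replicates. The top peak of the IDR list, 88 bp upstream of CG14100 on 3L, was ranked 1 in each replicate. The peaks in an intron of ush upstream of cbt and downstream of CG13323 were among the 3 strongest in each. Of the 8248 strongest peaks of a replicate, 80.2% ± 1.02 (SD over 6 ordered pairs of replicates, range 78.8% to 81.7%) were covered over at least 50% of their length by one of the 8248 strongest peaks of another. After circular shifts of the positions within each arm the share was 2.17% on average and at most 2.41% in 100 draws (two-sided permutation p = 0.02, the smallest that 100 shifts can give). Across the IDR peaks with a region in both lists, Spearman's rho between replicates was 0.863 for replicates 1 and 2, 0.870 for 1 and 3 and 0.860 for 2 and 3. Peaks are not independent replicates, and no test was made. The IDR peaks were selected for repeating between these same replicates, which favours a high rho.

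Most IDR peaks were found in every replicate. Of the 8248 peaks, 5820 (70.6%, exact binomial 95% interval 69.6% to 71.5%, counting error only) were covered over at least 50% of their length by a peak among the 8248 strongest of each replicate. Taken singly, 85.7% were covered in replicate 1, 87.3% in replicate 2 and 88.2% in replicate 3 (mean 87.1% ± 1.26, SD, n = 3), and 47 peaks were covered in none. Because the IDR list was made from these replicate lists, this is a description of the list and not an independent test of it.

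The strongest TSS-proximal peak lay at CG14100, with a signal of 3755 in the IDR list. The next in signal were at CG8320 (2976), Tcs5, a gene of tRNA modification (2850.05), Chro, which encodes the chromodomain protein Chromator of the spindle matrix and interbands (2819.9), PNPase, the mitochondrial polynucleotide phosphorylase (2794), and Hsp27, a small heat shock protein (2663). CenG1A, the mitochondrial ribosomal protein gene mRpL41, the arginine methyltransferase gene Art3, the UDP-galactose transporter gene Ugalt, the RNA-binding protein gene larp and CG1888 followed, with signals from 2624 down to 2278. The summit at CG14100 was at 3L:19590612, that at Chro at 3L:22878896, 88 bp downstream of its TSS, and that at Hsp27 at 3L:9383918, 145 bp upstream. Distal peaks, over 500 bp from a TSS, reached similar signals. The strongest had 3439 at 2L:481059, in an intron of ush and 1371 bp upstream of cbt, a zinc finger transcription factor. The next had 3331 at 2R:13035333, outside protein-coding genes, beyond the 3' end of CG13323 and 11923 bp from its TSS. The others were in introns of CG11050 (3043), of the MNK-type kinase gene Lk6 (2856), of the chromatin remodelling gene osa (2646), 13945 bp from its nearest TSS, and of HmgZ, a high mobility group protein (2284).

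Peaks lay at TSSs more often than positions chosen at random. Of the 8248 IDR summits, 2455 (29.8%, exact binomial 95% interval 28.8% to 30.8%) were within 500 bp of a TSS of a protein-coding gene, against 11.4% on average and at most 13.2% after 1000 circular shifts (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). Over the 8248 strongest peaks of each replicate the share was 31.6% ± 1.60 (SD, n = 3). The summits were mostly upstream: 83.5% of the 2455 lay on the upstream side, with a median position 134 bp before the TSS and quartiles at 240 and 56 bp before it, and the share upstream was 83.5% ± 1.45 in the replicates (SD, n = 3).

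Strong peaks were TSS-proximal more often than weak ones. Of the 2062 IDR peaks with the highest signal 39.4% were within 500 bp of a TSS, against 22.6% of the 2062 with the lowest, a difference of 16.8 percentage points (two-sided Fisher's exact test, p = 1.79e-31). The difference was 12.2, 15.3 and 13.6 percentage points in replicates 1, 2 and 3, with Fisher's exact p of 1.87e-16, 2.3e-26 and 2.13e-20. The share was 47.3% in the 825 strongest IDR peaks and 22.9% in the 824 weakest.

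**Figure D1:**
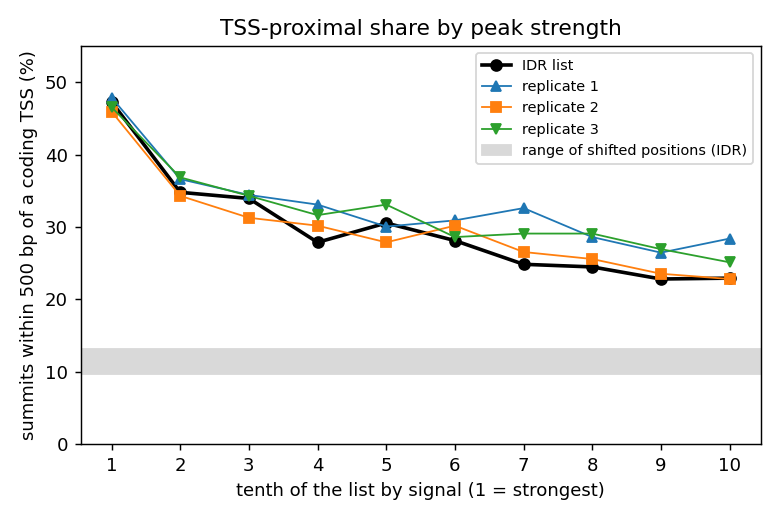
Share of summits within 500 bp of a protein-coding TSS (vertical axis, percent) in 10 bins of a list by the authors' signal value (horizontal axis, 1 is the strongest), for the IDR list and the 8248 strongest peaks of each replicate. The grey band is the range of the share over 1000 circular shifts of all IDR summits. The share falls from 47.3% to 22.9% in the IDR list, and all points lie above the band, whose top is at 13.2%. The band was drawn for the whole IDR list and not for a bin, which holds fewer peaks, or for a replicate.

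Summits were rare in coding exons and 3' UTRs. Introns held 3751 summits (45.5%, against 39.2% of shifted positions), while coding exons held 14 (0.17%, against 13.9%) and 3' UTRs 60 (0.727%, against 4.52%). Of all summits 23.4% lay outside protein-coding genes, against 30.1%. The share in 5' UTRs beyond 500 bp from a TSS was 0.436%, against 0.787%. Each of the 6 classes, promoters included, differed from the 1000 shifts (two-sided permutation tests with Benjamini-Hochberg adjustment over 6 classes, adjusted p from 0.0024, the smallest that the shifts can give here, to 0.004). In the replicates coding exons held 0.154% ± 0.0252 and introns 44.4% ± 0.894 of the strongest peaks (SD, n = 3). A comparison chosen after seeing the data used random positions with the same GC content as the summits: 3.52% of these were in coding exons and 7.38% in 3' UTRs (Fisher's exact p = 3.01e-69 and 1.77e-119 against the summits). The shares in introns, 44.2%, and in 5' UTRs, 0.63%, no longer differed detectably (Fisher's exact p = 0.114 and 0.108).

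**Figure D2:**
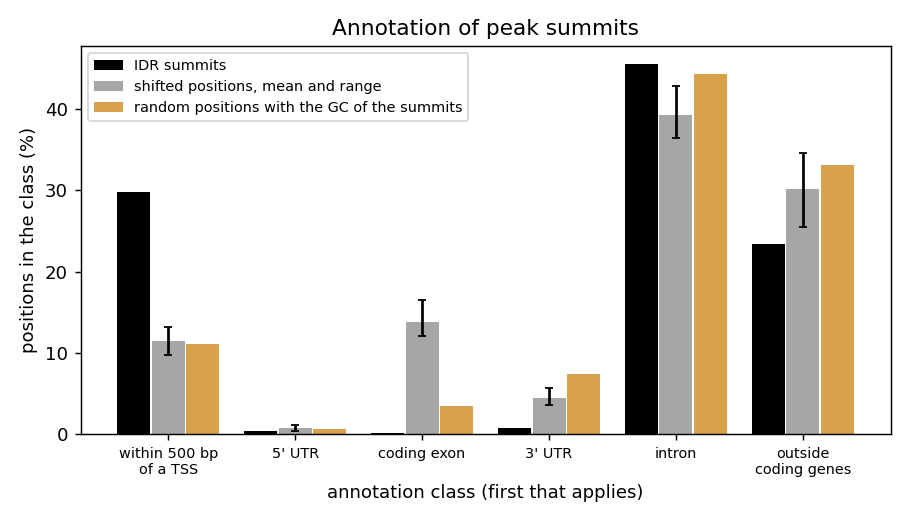
Share of positions (vertical axis, percent) in 6 annotation classes (horizontal axis) for the 8248 IDR summits, for 1000 circular shifts of them (mean, with the range as bars) and for random positions matched on GC content. Summits are more frequent than both within 500 bp of a TSS (29.8%) and rarer than both in coding exons (0.17%) and 3' UTRs (0.727%).

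The X chromosome, which carries acj6, held peaks at about the density of the autosomes. The IDR list had 65.4 peaks per Mb on X, against 65.7 on 2L, 54.3 on 2R, 66.6 on 3L and 59.0 on 3R, and 24 peaks in all on chromosome 4 (17.8 per Mb). The density on X was 1.07 times that of arms 2L, 2R, 3L and 3R together. The replicates differed in this: the ratio was 1.18 in replicate 2 and 0.981 and 0.990 in replicates 1 and 3 (mean 1.05 ± 0.111, SD, n = 3), so that X and the autosomes were not separable beyond the spread between replicates.

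Ribosomal protein genes carried peaks far more often than other genes, and genes of the chemical senses, of cuticle and of digestion less often. A summit lay within 1 kb of a TSS in 3399 of 13945 protein-coding genes (24.4%; replicates 25.6% ± 1.10, SD, n = 3). Among the 86 genes of cytoplasmic ribosomal proteins 61 were bound (70.9%, against 24.1% of all other genes; replicates 68.2% ± 5.85, SD, n = 3; two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 22 lists, adjusted p = 2.12e-18). The strongest peaks of the list were at RpS19b (signal 1072, 907 bp upstream and in an intron of its neighbour CG5854), RpL34b (678), RpL7 (619.6) and RpS27 (612). The other lists of genes used in most cells did not pass the main test: 6 of 48 proteasome genes (12.5%, adjusted p = 0.115) and 21 of 90 respiratory chain genes (23.3%, adjusted p = 0.992, Fisher's exact tests) were bound, although the respiratory chain share was above the 10.9% of shifted positions (adjusted permutation p = 0.022). The proteasome list was lower without replicate 3 (adjusted p = 0.041, Fisher's exact test) and passed in none of the other 8 alternatives.

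Of the olfactory receptor genes, a subset of which needs acj6 for its expression, 2 of 60 were bound (3.33%, adjusted p = 6.58e-05 by Fisher's exact test). These were Or9a (signal 134) and Or88a (118), each with a summit over 500 bp upstream and closer to another gene's TSS. The samples were whole white prepupae, so this count cannot tell whether acj6 binds these genes in olfactory neurons or at other stages. The ionotropic receptors had 1 bound gene of 60, Ir94h (signal 389.7), and the gustatory receptors 1 of 60, Gr77a (134), each with an adjusted p of 1.28e-05 by Fisher's exact test. Of the odorant-binding proteins 3 of 52 were bound (adjusted p = 0.00291 by Fisher's exact test), with Obp83g (329) and Obp99b (327) strongest. Cuticle protein genes had 7 bound of 137 (5.11%, adjusted p = 2.74e-08), led by Cpr72Eb (495) and Cpr62Ba (317), and secreted digestive enzymes 1 of 44 (adjusted p = 0.000472, Fisher's exact tests), the maltase gene Mal-A5, whose peak was higher in signal (1116). All 7 differences had the same direction in 3 of 3 replicates. Against circular shifts of the peaks in place of other genes the ribosomal protein call held (adjusted permutation p = 0.022), and the 6 lower lists did not pass (adjusted permutation p from 0.0824 to 0.625): random positions met 10.2% to 11.4% of their genes.

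The lists of neuronal genes did not pass the main test. Of 112 genes of axon guidance and synaptic partner choice 23 were bound (20.5%, adjusted p = 0.554), of 42 neuron markers 9 (21.4%, adjusted p = 0.992), of 23 glia markers 7 (30.4%, adjusted p = 0.611) and of 44 proneural and Notch pathway genes 14 (31.8%, adjusted p = 0.456, all Fisher's exact tests). None of 17 genes of cholinergic transmission was bound (adjusted p = 0.0523 by Fisher's exact test). Of 70 transcription factors listed for neuron identity, with homeodomain, POU and LIM factors among them, 9 were bound (12.9%, adjusted p = 0.0546 by Fisher's exact test). Their strongest peaks, named after the values were seen, were at Poxm (889.8), a paired-box gene of muscle development, the BTB zinc finger gene lola (757), dsx (269.8), a DM-domain gene of sex determination, and the BTB zinc finger gene mamo (239.7), none of them a homeodomain, POU or LIM factor. With gene length and TSS number as covariates in a logistic regression, 4 of these lists passed as lower: axon guidance (odds ratio 0.406), neuron markers (odds ratio 0.284), neuron identity (odds ratio 0.194) and cholinergic transmission, with no bound gene. The neuron identity list was lower with a distance of 500 bp (adjusted p = 0.0303) and higher when summits anywhere in the gene body and 2 kb around it were counted (adjusted p = 0.00518, Fisher's exact tests), and the proneural and Notch list was higher against circular shifts (adjusted permutation p = 0.022).

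Genes of the response to ecdysone, the steroid hormone that triggers puparium formation, were bound in 20 of 52 cases (38.5%, against 24.3% of other genes; replicates 39.1% ± 2.22, SD, n = 3), short of the threshold (Fisher's exact test, adjusted p = 0.0546). Their strongest peaks, also named after the values were seen, were at Sox14 (1685), a transcription factor early in the response, the transporter gene E23 (1158), the lactate dehydrogenase gene Ldh (882) and the cell death gene hid (845). The list passed as higher in 8 of 9 alternatives, among them the 5820 peaks found in all 3 replicates (adjusted p = 0.0184) and each set without 1 replicate (adjusted p from 0.0242 to 0.0393, Fisher's exact tests). These alternatives reuse the same peaks, so the 8 calls are not independent of each other. The ecdysone list did not pass with gene length and TSS number as covariates, where its odds ratio was 1.18. The remaining lists did not pass the main test: 14 of 49 genes of imaginal disc signalling (adjusted p = 0.618), 7 of 31 muscle genes (adjusted p = 1), 6 of 25 heat shock genes (adjusted p = 1), 6 of 18 fat body genes (adjusted p = 0.563), 0 of 12 salivary glue genes (adjusted p = 0.0945) and 0 of 8 Hox genes (adjusted p = 0.359, Fisher's exact tests). Counting summits in the gene body and 2 kb around it, imaginal disc signalling was higher (adjusted p = 1.24e-06) and salivary glue lower (adjusted p = 0.012, Fisher's exact tests). With gene length and TSS number as covariates, muscle structure (odds ratio 0.325) and the Hox genes, with none bound, passed as lower.

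**Figure D3:**
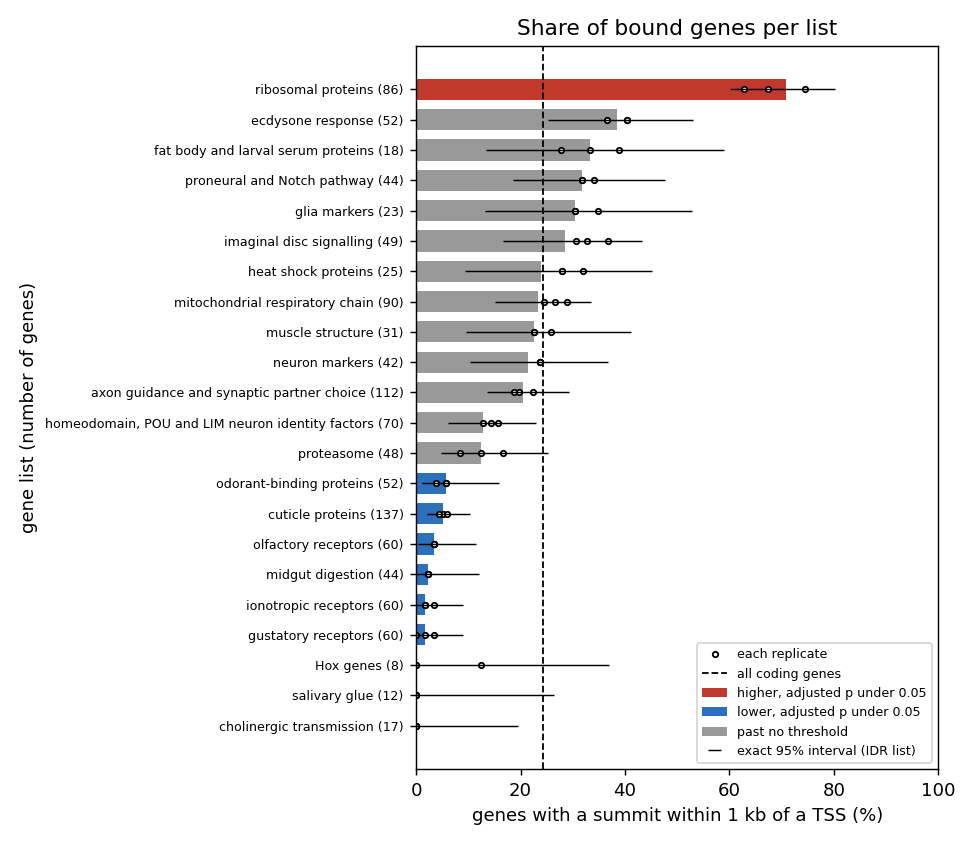
Share of genes with a summit within 1 kb of a TSS (horizontal axis, percent) for 22 gene lists fixed before the data were examined (vertical axis, number of genes in brackets), with bars for the IDR list, exact 95% intervals for counting error, open points for each replicate and a dashed line for all 13945 genes (24.4%). Ribosomal protein genes (70.9%) stand above the line in every replicate, and the 6 lists in blue lie below it.

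The class IV POU site was not detectably more frequent at all IDR summits than beside them. A match to GCATAATTAAT with at most 1 mismatch lay within 100 bp of 106 summits (1.29%) and in 86 windows centred 1 kb to the right (1.04%; two-sided exact McNemar test with Benjamini-Hochberg adjustment over 15 motifs, adjusted p = 0.229). The short form ATTAATGAG was found at 30 summits and in 22 control windows (adjusted p = 0.383), and the octamer ATGCAAAT at 262 and 282 (adjusted p = 0.438, exact McNemar tests). In the stronger 4124 peaks the long site passed as higher, with 1.31% of summits and 0.727% of control windows (ratio 1.8, adjusted p = 0.0228, exact McNemar test). It passed in none of the other 7 alternatives (ratios from 0.946 to 1.43, adjusted p from 0.0614 to 0.917). The long site was present at 76 of 5793 distal peaks (1.31%) and at 30 of 2455 TSS-proximal ones (1.22%), a difference of 0.0899 percentage points (two-sided Fisher's exact test, p = 0.831). The distal and TSS-proximal shares were 1.26% and 0.995% in replicate 1 and 1.39% and 1.13% in replicate 3. In replicate 2 they went the other way, at 1.21% and 1.46% (Fisher's exact p from 0.328 to 0.352 in the 3 replicates). In simulated data the test found a larger excess than the one observed, with the long site in 2.28% of windows after planting and in 1.27% of controls (adjusted p = 1.8e-05, exact McNemar test). An excess as small as the observed one was not simulated.

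Summits were rich in A and T. The GC content within 100 bp of the summit was 34.0%, against 41.8% 1 kb away (replicates 34.2% ± 0.367 and 41.9% ± 0.0985, SD, n = 3). TATAAA was found at 39.3% of summits and in 22.5% of control windows (adjusted p = 1.99e-117, exact McNemar test), and the homeodomain core TAATTA at 18.4% and 13.6% (adjusted p = 5.06e-16, exact McNemar test). The DRE site TATCGATA of housekeeping promoters was found at 1.76% and 0.497% (adjusted p = 4.02e-14, exact McNemar test), through TSS-proximal peaks (5.05% against 0.407%) and not distal ones (0.363% against 0.535%). Motif 1 (0.752% against 0.279%, adjusted p = 6.54e-05) and GATA (6.2% against 5.26%, adjusted p = 0.0175, exact McNemar tests) were also higher, and GATA passed in 1 of 8 alternatives, with ratios from 1.08 to 1.2 in the others. Motif 1 was higher at TSS-proximal summits (1.83% against 0.326%, adjusted p = 8.88e-07) and did not pass at distal ones (0.293% against 0.259%, adjusted p = 0.856, exact McNemar tests). GATA passed at distal summits (6.04% against 5.01%, adjusted p = 0.0403) and not at TSS-proximal ones (6.56% against 5.87%, adjusted p = 0.566, exact McNemar tests). GAGA, the E-box CAGCTG, the Zelda, ecdysone receptor and grainy head sites were lower, at 0.768, 0.752, 0.67, 0.741 and 0.825 times the control share (adjusted p from 4.99e-07 to 0.0264, exact McNemar tests). The Zelda site passed in 1 of 8 alternatives, with ratios from 0.657 to 1.2 in the others, and the grainy head site in 4 of 8, with ratios from 0.858 to 0.985 in the others. GAGA (2.23% against 3.56%, adjusted p = 8.6e-05) and the E-box (5.14% against 8.42%, adjusted p = 1.3e-11) were lower at distal summits, and at TSS-proximal ones had 4.48% against 4.28% and 10.3% against 9.9% (adjusted p = 0.9 for each, exact McNemar tests). The ecdysone receptor site was lower at TSS-proximal summits (2.24% against 4.52%, adjusted p = 2.97e-05) and did not pass at distal ones (3.4% against 3.95%, adjusted p = 0.261, exact McNemar tests). Each of these 10 motifs had the same direction in 3 of 3 replicates.

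Against summits of weak pooled peaks matched on GC content, the DRE was higher (1.76% against 1.1%, ratio 1.59, adjusted p = 0.00364, Fisher's exact test). These weak peaks were not matched on position, and 15.8% of all weak pooled peaks were TSS-proximal, against 29.8% of IDR peaks. They come from the same immunoprecipitation and may include weaker sites of the same factor. A ratio near 1 against them therefore does not show that base composition accounts for a motif. With the same matching, TATAAA (ratio 1, adjusted p = 1), TAATTA (ratio 0.933, adjusted p = 0.0964), Motif 1 (ratio 1.59, adjusted p = 0.0964), GATA (ratio 1.08, adjusted p = 0.42), the ecdysone receptor site (ratio 0.897, adjusted p = 0.42), the Zelda site (ratio 1.2, adjusted p = 0.537) and the grainy head site (ratio 0.985, adjusted p = 0.985) did not pass (Fisher's exact tests). GAGA and the E-box turned round, at 1.38 and 1.29 times the control share (adjusted p = 0.00579 and 0.000959, Fisher's exact tests). Among all 2080 6-mers, 572 were more and 1128 less frequent at summits than 1 kb away (exact McNemar tests, Benjamini-Hochberg adjusted p under 0.05); against the GC-matched weak summits it was 158 and 119. The highest ratios were those of AGTGTA (2.39), ACACTG (2.29), ATATTA (2.2), ACAGTG (2.17), AGGGTA (2.14) and AATATA (2.03), and the lowest those of CCCGGG (0.264), CCCCGG (0.265), CCCGGC (0.271) and CCGGCC (0.275). With GC matched, ACAGTG (1.53, adjusted p = 2.91e-25) and ACACTG (1.44, adjusted p = 5.59e-18, Fisher's exact tests) kept ratios further from 1 than the AT-only words ATATTA (1.1) and AATATA (1.05).

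The numbers of peaks per arm were similar in the older build. The dm3 IDR list held 7931 peaks, 317 fewer than the dm6 list, and the share per arm differed little: 18.8% against 18.7% on X, 18.8% against 18.7% on 2L and 22.6% against 22.7% on 3L. No coordinates were converted, so no peak was matched between the builds, and positions were read only in dm6.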

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

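The dm3 IDR list held 4 peaks outside the main arms, which no comparison used: 2 on the unplaced sequence U, 1 on 3LHet and 1 on XHet. They were flagged only because they are signal in data left aside and number more than 3. The other dm3 lists, of 30000 regions each, held from 68 to 123 regions outside the main arms. The dm6 lists held no region outside the main arms.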

How the results depend on the processing

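All alternatives for 6-mers and for annotation classes were chosen after seeing the data. Agreement of replicates, the TSS-proximal share, its difference between strong and weak peaks, the X ratio and the distal difference of the POU-IV site kept their direction and side of the threshold (the X ratio, which has no test, stayed within 1 SD) under every alternative run for them, except that the X ratio was 0.985 without replicate 2. The cause of the changes below was not tested. The share of IDR peaks found in all 3 replicates was 76.6% with an overlap of 1 bp, 68.5% with summits within 100 bp, 91.0% in the stronger 4124 peaks, and from 76.6% to 78.3% when 1 replicate was left out, which asks for fewer lists. In the stronger 4124 peaks introns held 43.9% and coding exons 0.121%; coding exons held 0.12% of peaks found in all 3 replicates and from 0.124% to 0.172% without 1 replicate. The lists bound more often numbered 2 instead of 1 in the stronger 4124 peaks, in peaks found in all 3 replicates, at 500 bp and without any 1 replicate (from 2 to 2), the added list being the ecdysone response. They numbered 4 by gene body and 2 kb around it and 4 against circular shifts. The lists bound less often were 0 instead of 6 against circular shifts 12 in the logistic regression, 7 at 500 bp and by gene body, and from 6 to 7 without 1 replicate (the proteasome was added without replicate 3). Motifs lower at summits numbered 3 instead of 5 in peaks found in all 3 replicates and against windows to the left, from 3 to 5 without 1 replicate, and 0 against GC-matched weak summits, where 3 were higher; there GAGA (1.38) and the E-box (1.29) reversed. The 6-mers then numbered 158 higher and 119 lower. Unknown read depth limits all counts of weak peaks.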

Other observations

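The word TCAGTG and its position, the tests of transposable elements and of the initiator, of housekeeping genes, and of distal peaks and the short POU site were chosen after their results, or results close to them, had been seen; the tests of gene length, of the strongest peaks and of non-coding RNA starts were set down before.

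Distal peaks lay near starts of non-coding RNA genes more often than by chance. Of the 5793 distal summits 3.8% were within 500 bp of the start of one of 3261 annotated non-coding RNA genes, against 2.06% of shifted positions on average and at most 2.83% in 1000 shifts (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). A small part of the distal peaks may therefore be promoters of such genes, while most distal peaks lie elsewhere.

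The word TCAGTG, reading away from the summit, began 40 to 100 bp from 729 of 5793 distal summits (12.6%) and in the opposite orientation from 142 (2.45%), a ratio of 5.13 (exact 95% interval 4.28 to 6.19). In this window, chosen where the word is most frequent, the ratios were from 4.59 to 4.91 in the 3 replicates, from 4.15 to 7.5 on the 5 large arms, 1.86 at TSS-proximal summits and 2.18 at weak distal pooled peaks; over 20 to 300 bp the ratio of occurrences was 2.79 at distal summits (2.56 to 3.06) and 1.52 at TSS-proximal ones. Base composition alone would give a ratio near 1, and the ratio of 2.79 over 20 to 300 bp, which depends less on the chosen window, argues against it. The word and its orientation were picked in these same summits, so the size of either ratio may be too high. Of the 729 summits 1 (0.137%) lay in an annotated transposable element, which argues against copies of annotated elements. The share of all distal summits in such elements was not set beside it. Promoters missing from the annotation stay open: the common initiator TCAGTT had a ratio of 1.17 at distal summits (0.971 to 1.4) and 1.09 at TSS-proximal ones (0.822 to 1.45) over 40 to 100 bp, and 1.15 (1.06 to 1.25) and 1.5 (1.32 to 1.69) over 20 to 300 bp, a window set after the narrower one had shown no excess of either orientation at TSS-proximal summits, and over all distal summits it decides nothing about the 729. No biological explanation was tested.

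Ribosomal protein genes were bound in 70.9% of cases. Open promoters of housekeeping genes in general would raise proteasome and respiratory chain genes as well, of which 19.6% were bound (exact 95% interval 13.3% to 27.2%). These shares were known when the comparison was chosen, and no measure of open chromatin entered it. Against shifted positions the respiratory chain share was higher (23.3% against 10.9%, adjusted permutation p = 0.022), and the proteasome share did not pass (12.5% against 10.2%). A part played by such promoters is therefore not excluded, but these lists argue against them as the whole cause. With gene length and TSS number as covariates the odds ratio was 8.55 (5.29 to 13.8), which argues against these covariates as the whole cause. Whether any GFP-tagged protein gives peaks at the most highly transcribed genes stays open, since a GFP control was not analysed here, and no biological explanation was tested. For the same reason it stays open whether the strongest peaks, the DRE excess and the TCAGTG word are particular to acj6.

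The class IV POU site was not detectably enriched over all peaks. The ratio of peaks with the site at the summit alone to those with it 1 kb away alone was 1.09 in distal peaks (exact 95% interval 0.773 to 1.53), 1.59 in the strongest 2062 peaks (0.835 to 3.11) and 1.36 for the short site over all peaks (0.761 to 2.48). Dilution by TSS-proximal peaks, dilution by weak peaks and a consensus longer than the site cannot be told apart from absence of enrichment, because each interval includes both 1 and 1.5; TSS-proximal peaks had the site at 1.22% of summits and in 0.652% of control windows (adjusted p = 0.116, exact McNemar test) and distal ones at 1.31% and 1.21%, the opposite of what dilution by TSS-proximal peaks needs, but the difference between these excesses was not tested. The stronger 4124 peaks did pass (ratio 1.8, adjusted p = 0.0228, exact McNemar test), but their share of summits with the site, 1.31%, was close to the 1.29% of all peaks, and it was the control windows that differed (0.727% and 1.04%). No biological explanation was tested.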
